A study of Homo sapiens with 40 samples.

How the data were processed

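The samples were human H1 embryonic stem cells, an established line, taken through an interneuron protocol with SMAD inhibitors, Shh and purmorphamine, and then BDNF, GDNF, NT3 and cAMP. Populations of cells were sorted by FACS as Citrine-positive (labelled DCX+) or Citrine-negative (DCX-) at D26, D54 or D100, and polyA RNA was amplified by the SmartSeq2 protocol. Some DCX+ populations came from co-culture with astrocytes, whose species is not given in the sources used here. The series text also speaks of single cells, which were not used here. The deposited table gives TPM, which the authors computed with RSEM and Bowtie against hg19, per the submitters' processing notes, which state no versions. It has 23045 features by gene symbol for 40 libraries, and each column sums to 1000000, so TPM keeps no depth and no counting interval or floor could be given. Of the features, 3826 were 0 in every library. The 10 most abundant features took from 13.4% to 21.7% of a library, and TVAS5 alone, which the table lists beside the genes, took from 3.43% to 7.21%.

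Groups were taken from the labels: 8 states (fraction, day and co-culture) and the label 50P/S or 100P/S, with batches 1 to 4 of 9, 16, 14 and 1 libraries. Batch here is the replicate number of the label, and neither sequencing runs nor separate cultures are named. Residuals of libraries with the same number had a mean correlation of 0.05 over 230 pairs against -0.03 over 465 pairs with different numbers, and a replicate block was tried as an alternative. No columns were identical, and the highest correlation between libraries was 0.977. The first principal components took 33.9% and 16.9% of the variance.

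Values were analysed as log2(TPM + 1), which understates fold changes of genes near 1 TPM, over the 15662 genes with at least 1 TPM in at least 3 libraries. A linear model with the 8 states and an additive P/S term was fitted to all 40 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend. P-values were adjusted over genes by Benjamini and Hochberg within each of 13 contrasts, and a gene was called at an adjusted p under 0.05. There were 10 comparisons and 3 differences of differences. The 28 gene lists, written before the data were examined, had 464 members, all in the table, and 410 were tested. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 28 lists, and "adjusted over the list alone" means Benjamini and Hochberg over a list's members. SLC1A3 and some others are in more than 1 list. Changes of log2 1 and 2 were simulated on this design in 100 genes each of 15662. Recovered were 59% and 92% for the sort at D26 and 93% and 100% for P/S. For co-culture these were 60% and 89% at D54, and 46% and 88% at D100. Recovery near 1 TPM is unknown.

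The genes named were set by a rule before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 TPM in 1 of the states compared and the same direction in every batch holding both. It added up to 4 members of each list with the smallest adjusted p, and always a fixed set of markers, DCX, SOX2, MKI67, NKX2-1, LHX6, DLX2, GAD1 and SST among them. Some genes that met the rule are not reported here. The text names list members from called lists only as far as room allowed. Members of gene families, histone genes and small nucleolar RNA genes are less certain, since reads shared between copies were assigned by the authors' software. A value listed at 0 in a whole group has no fold change.

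The 4 libraries labelled 50P/S D54 and 100P/S D26 in batch 2 were kept under their labels, and leaving them out was added after the data were seen, as was a random term by culture for P/S (libraries of the same number, day, P/S label and co-culture, with an estimated correlation of 0.19). The other alternatives were set before: pseudocounts of 0.1 and 5, no filter or at least 5 TPM, median-of-ratios scaling, quantile normalization and a replicate block. Further ones were the 16 label combinations as groups, the compared libraries alone, batch 2 or batch 3 alone, a block by culture for the sort, P/S within each kind of library, and each library left out in turn. Other splits of the same libraries, at most 100 per contrast with a fixed seed, were refitted. The reference genome supplied was of another build than hg19 and was not used here, so no coordinates are given.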

Results

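The data were 40 polyA RNA-seq libraries from human H1 embryonic stem cells differentiated under a ventralizing protocol towards interneurons, a route that uses SMAD inhibition, Shh and purmorphamine. A Citrine reporter separated cells labelled DCX+ (neurons) from cells labelled DCX- (progenitors), and each library came from a sorted population of cells. The DCX- libraries numbered 5 at day 26 (D26), 5 at D54 and 3 at D100. The DCX+ libraries numbered 5 at D26, 7 at D54 and 5 at D100 without astrocytes, and 6 at D54 and 4 at D100 from co-culture with astrocytes. Of the 40 libraries, 22 carried the label 50P/S and 18 the label 100P/S, an abbreviation whose meaning is not given in the sources used here. Values were in TPM, a length-scaled share of transcripts, which sum to the same total in every library, so the sequencing depth is unknown. Each library had between 11237 and 13512 features at 1 TPM or more, and features named as rRNA held from 3.24% to 8.41% of the total. Log2 fold changes (with SE) are on log2(TPM + 1) with the P/S label as a term, TPM levels are means with SD, and adjusted p-values are from limma. Gene lists were tested by camera with a preset correlation, and a second adjusted p is given with an estimated correlation between genes. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples.

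For 4 libraries of batch 2 the expressed genes stood with another day than the label. A score of 50 genes per direction, set to 0 at the mean of the other D26 libraries of a fraction and to 1 at that of the other D54 libraries, placed 0 of the 18 other libraries nearer the other day. The genes and both means were taken without the library scored and without the 4. The libraries labelled 50P/S D54 in batch 2 scored 0.04 in DCX+ and 0.03 in DCX-, and those labelled 100P/S D26 in batch 2 scored 0.94 and 0.91. The groups below follow the labels as deposited, and the number of genes called in each comparison is also given without these 4 libraries.

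**Figure D1:**
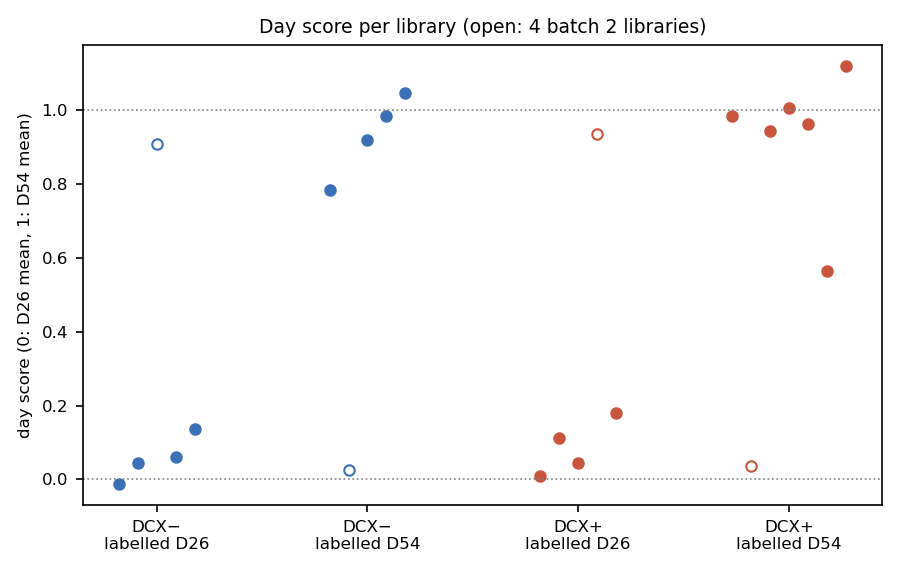
Day score of each DCX+ and DCX- library labelled D26 or D54 without astrocytes, where 0 is the mean of the D26 libraries and 1 that of the D54 libraries of the same fraction, both without the 4 batch 2 libraries drawn as open symbols. The other 18 libraries lie from -0.01 to 0.18 when labelled D26 and from 0.56 to 1.12 when labelled D54, and the 4 open symbols lie at the level of the other day.

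The reporter sort asked how DCX+ neurons differ from DCX- progenitors, and it was read at each day (5 against 5 libraries at D26). At D26, DCX+ cells held 1217 ± 267 TPM of STMN2, a regulator of neuronal microtubules, against 29.5 ± 15.96 TPM in DCX- cells (log2 fold change 5.47 ± 0.30, adjusted p = 4.21e-16). ACTL6B, a subunit of the neuronal BAF chromatin remodelling complex, was higher by 5.41 ± 0.42, the presynaptic SNARE gene SNAP25 by 5.15 ± 0.48, the membrane protein gene RTN1 by 4.98 ± 0.33 and the netrin receptor gene DCC by 4.70 ± 0.42. GAD1, which makes GABA, was higher by 4.69 ± 0.62, adjusted p = 3.77e-07, and LHX6, a factor of medial ganglionic eminence (MGE) interneurons, by 4.43 ± 0.59, adjusted p = 4.85e-07. DCX itself was higher by 3.44 ± 0.32, adjusted p = 2.99e-10, at 88.7 ± 20.1 against 8.15 ± 4.597 TPM. The neuropeptide gene SST (5.13 ± 1.21, adjusted p = 0.00145), the reductase gene AKR1C2 (4.79 ± 0.31), the homeobox gene DLX2 (2.28 ± 0.53, adjusted p = 0.00129) and DLX6-AS1 (5.36 ± 0.58) were also higher. DLX6-AS1 overlaps DLX6, and values without strand cannot tell such pairs apart. DCX- cells held more of the mitotic genes TROAP (-3.88 ± 0.42), NDC80 (-3.74 ± 0.62), TTK (-3.73 ± 0.53) and DLGAP5 (-3.45 ± 0.51), and of ID1 (-3.55 ± 0.83) and ID3 (-3.46 ± 0.81), inhibitors of proneural factors. MKI67, a proliferation marker, was lower in DCX+ (-1.82 ± 0.47, adjusted p = 0.00308), as was SOX2, a progenitor factor (-1.15 ± 0.33, adjusted p = 0.00773). The histone gene HIST1H3B was listed at 0 in all 5 DCX+ libraries against 10.8 ± 4.37 TPM. NKX2-1, an MGE factor, did not pass the test (0.08 ± 0.90, adjusted p = 0.973). Without 100P/S DCX+ D26 replicate 2, 1 of the 4, SST was higher by 3.799, and without all 4 by 4.59 ± 0.69, adjusted p = 5.35e-06.

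Of 15662 genes tested at D26, 4023 differed, 1794 higher and 2229 lower in DCX+. The sign was the same in each of the 3 batches holding both fractions for 3834 of them, and 3950 genes differed without the 4 batch 2 libraries. A fit to the compared libraries alone gave 2191 genes and a block by culture 2500. Among 18 pan-neuronal genes 16 were higher and 0 lower, or 16 and 1 adjusted over the list alone (median 3.09, adjusted p = 4.74e-18 and adjusted p = 0.00684 with an estimated correlation). Of 22 presynaptic genes 15 were higher, among them RAB3A (3.95 ± 0.32) and NAPB (3.46 ± 0.28), and 16 adjusted over the list alone (adjusted p = 6.38e-13 and adjusted p = 0.0759 with an estimated correlation). GABA synthesis and transport had 4 of 8 genes higher (adjusted p = 8.01e-04 and adjusted p = 0.146 with an estimated correlation). The MGE list had 7 of 15 (adjusted p = 0.00292 and adjusted p = 0.148 with an estimated correlation). GABA and glycine receptors had 7 of 18 higher (adjusted p = 5.26e-04 and adjusted p = 0.223 with an estimated correlation). Glutamate receptors had 7 of 19 higher (adjusted p = 5.26e-04 and adjusted p = 0.265 with an estimated correlation). Voltage-gated channels had 7 of 21 higher (adjusted p = 6.58e-04 and adjusted p = 0.213 with an estimated correlation).

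All 22 cell cycle genes were lower in DCX+ at D26, PCNA for example at -2.22 ± 0.23 (median -2.94, adjusted p = 1.04e-20 and adjusted p = 0.0759 with an estimated correlation). The radial glia list had 14 of 20 lower, such as HES5 (-2.81 ± 0.54) and FABP7 (-2.71 ± 0.52), with adjusted p = 2.27e-07 and adjusted p = 0.0773 with an estimated correlation. The interferon list had 7 of 17 lower, B2M at -2.11 ± 0.34 among them (adjusted p = 0.00279 and adjusted p = 0.126 with an estimated correlation). Without the 4 batch 2 libraries 3 lists lost their calls. The interneuron subtype list, 7 of 26 higher and 1 lower (adjusted p = 0.0343 and adjusted p = 0.476 with an estimated correlation), fell to adjusted p = 0.152. Cholinergic genes, 3 of 7 higher (adjusted p = 0.0296 and adjusted p = 0.126 with an estimated correlation), fell to adjusted p = 0.0587. Unfolded protein and amino acid stress genes, 7 of 18 lower and 1 higher (adjusted p = 0.0412 and adjusted p = 0.472 with an estimated correlation), fell to adjusted p = 0.159. Glycolysis genes missed the threshold with 6 of 20 lower (adjusted p = 0.0512) and passed it with a replicate block (adjusted p = 0.0371). Quantile normalization ended the interneuron subtype and stress calls too (adjusted p = 0.0628 and 0.0624).

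The other 14 lists were not called at D26. Pluripotency had 1 of 8 higher and 1 lower (adjusted p = 0.816). LGE and CGE factors had 4 of 13 higher (adjusted p = 0.209). Hypothalamic, midbrain and floor plate factors had 1 of 4 higher (adjusted p = 0.0965), cortical glutamatergic genes 1 of 7 higher and 1 lower (adjusted p = 0.674), and monoaminergic genes 2 of 6 higher (adjusted p = 0.0759). SHH targets had 1 of 7 higher and 3 lower (adjusted p = 0.10005). Notch and proneural genes had 3 of 12 higher and 5 lower (adjusted p = 0.881), with a median of 0.06 and a mean of 0.09 against a test pointing down. Oligodendrocyte genes had 1 of 14 lower (adjusted p = 0.6902), and astrocyte genes 1 higher and 1 lower of 14 (adjusted p = 0.414). Mesenchymal genes had 6 of 12 lower (adjusted p = 0.0716), and endothelial, blood and microglial genes 1 of 4 (adjusted p = 0.657). Immediate early and heat shock genes had 1 of 16 higher and 1 lower (adjusted p = 0.674). Nuclear oxidative phosphorylation had 2 of 22 higher and 1 lower, with a median of -0.07 against a mean of 0.02 (adjusted p = 0.661). Cholesterol synthesis had 3 of 20 lower (adjusted p = 0.148). RPL21 met the naming rule (-4.70 ± 1.60, adjusted p = 0.0263) but rested on batch 2, with -10.72 there, -0.66 in batch 1 and -0.71 in batch 3. Its call was lost in 4 of 10 fits that left out 1 library, with adjusted p = 0.154 without 100P/S DCX+ D26 replicate 2, and it stood at adjusted p = 0.127 without the 4 batch 2 libraries.

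At D54 the same comparison (7 against 5 libraries) was led by the neuropeptide precursor gene TAC1 (4.50 ± 0.68, adjusted p = 2.49e-06) and FXYD7, a regulator of the sodium pump (4.50 ± 0.45, adjusted p = 1.52e-09). SST stood at 10756 ± 7592 TPM in DCX+ cells against 543 ± 466 (4.19 ± 1.13, adjusted p = 0.00385). Its log2 fold change was 3.16 without 50P/S DCX- D54 replicate 2 and 5.04 without 50P/S DCX+ D54 replicate 2, 2 of the 4. STMN2 (4.18 ± 0.27), DLX6-AS1 (4.30 ± 0.54), the neurexin ligand gene NXPH1 (4.10 ± 0.79), the calretinin gene CALB2 (4.04 ± 0.71) and the secretory granule gene PTPRN (4.02 ± 0.30) were higher. LHX6 (3.46 ± 0.55, adjusted p = 6.16e-06), GAD1 (3.24 ± 0.58, adjusted p = 3.17e-05) and DCX (2.98 ± 0.30, adjusted p = 1.49e-09) were higher as well, while DLX2 missed the threshold (1.20 ± 0.50, adjusted p = 0.0634), which it passed in 7 of 25 other settings (lowest adjusted p = 0.01298). DCX- cells held more of S1PR1, a sphingosine phosphate receptor (-5.31 ± 0.64, adjusted p = 5.58e-08), the adhesion gene VCAM1 (-5.31 ± 0.68), the glial glutamate transporter gene SLC1A3 (-5.03 ± 0.78), PPAP2B (-4.83 ± 0.54) and the glypican gene GPC3 (-4.77 ± 0.87). The endothelin receptor gene EDNRB (-4.76 ± 0.56) and LIX1 (-4.62 ± 0.43) followed. SOX2 (-1.23 ± 0.31, adjusted p = 0.0018005) and MKI67 (-2.18 ± 0.43, adjusted p = 1.45e-04) were lower in DCX+, and NKX2-1 (-0.77 ± 0.84, adjusted p = 0.546) did not pass. Outside the 4, 100P/S DCX+ D54 replicate 1 stood apart from the other 5 DCX+ libraries, with 1815 TPM of SST (others 8752 to 19820) and a day score of 0.56. It also held 885 TPM of VIM (others 27.0 to 198), 398 of CTGF (0 to 18.6) and 151 of TAGLN (0.57 to 3.14), genes looked at after its values were seen. It was kept, and leaving it out gave 4909 genes for this sort, 950 for D54 against D26 and 861 for D100 against D54 in DCX+, and 142 for P/S.

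In total, 4932 genes differed at D54, 2133 higher and 2799 lower in DCX+. The sign was the same in all 3 batches for 4742, and 5161 genes were called without the 4 batch 2 libraries. The calls of 7 lists held with an estimated correlation. Pan-neuronal genes were higher for 16 of 18 (adjusted p = 1.18e-15 and adjusted p = 0.0154 with an estimated correlation), and presynaptic genes for 18 of 22 (adjusted p = 2.15e-14 and adjusted p = 0.0293 with an estimated correlation). GABA and glycine receptors were higher for 15 of 18 (adjusted p = 1.28e-09 and adjusted p = 0.0397 with an estimated correlation). Cholinergic genes were higher for 5 of 7, led by ACHE at 3.51 ± 0.33 (adjusted p = 0.002203 and adjusted p = 0.0293 with an estimated correlation). Cell cycle genes were lower for 22 of 22 (adjusted p = 8.77e-19 and adjusted p = 0.0454 with an estimated correlation), and radial glia genes for 17 of 20, HES1 at -3.57 ± 0.39 (adjusted p = 1.22e-10 and adjusted p = 0.0293 with an estimated correlation). Interferon genes were lower for 9 of 17 (adjusted p = 2.97e-04 and adjusted p = 0.0454 with an estimated correlation).

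Other lists at D54 lost the call with an estimated correlation. GABA synthesis had 5 of 8 genes higher and 1 lower (adjusted p = 0.00539 and adjusted p = 0.17003 with an estimated correlation). Interneuron subtype genes were higher for 14 of 26 (adjusted p = 7.32e-05 and adjusted p = 0.149 with an estimated correlation). Glutamate receptors were higher for 12 of 19, GRIA1 at 3.27 ± 0.36 (adjusted p = 3.09e-07 and adjusted p = 0.106 with an estimated correlation). Channels were higher for 11 of 21 (adjusted p = 4.67e-06 and adjusted p = 0.0732 with an estimated correlation). Monoaminergic genes were higher for 3 of 6, TH and DDC at 3.07 ± 0.76 and 2.79 ± 0.68 (adjusted p = 0.036997 and adjusted p = 0.118 with an estimated correlation). Oxidative phosphorylation had 11 of 22 higher (adjusted p = 0.00119 and adjusted p = 0.118 with an estimated correlation). Astrocyte genes were lower for 7 of 14, GJA1 at -3.82 ± 0.53, while SLC1A2 was higher at 2.24 ± 0.44 (adjusted p = 0.00639 and adjusted p = 0.1902 with an estimated correlation). Glycolysis had 11 of 20 lower (adjusted p = 0.00751 and adjusted p = 0.405 with an estimated correlation). Unfolded protein and amino acid stress had 8 of 18 lower, PHGDH at -2.05 ± 0.24 (adjusted p = 0.00412 and adjusted p = 0.257 with an estimated correlation). Cholesterol synthesis had 9 of 20 lower, DHCR7 at -1.12 ± 0.24 (adjusted p = 0.00224 and adjusted p = 0.368 with an estimated correlation). SHH targets had 3 of 7 lower (adjusted p = 0.0397 and adjusted p = 0.134 with an estimated correlation), a call lost with a replicate block (adjusted p = 0.0511) and without the 4 libraries (adjusted p = 0.122). Mesenchymal genes had 6 of 12 lower, with THY1 higher at 1.63 ± 0.30 (adjusted p = 0.0476 and adjusted p = 0.368 with an estimated correlation). That call was lost with a replicate block (adjusted p = 0.0653) and without the 4 libraries (adjusted p = 0.0985). Quantile normalization ended the monoaminergic call (adjusted p = 0.0602).

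At D100 (5 against 3 libraries) CRABP1, a retinoic acid binding protein gene, led with 3639 ± 2372 TPM in DCX+ against 51.5 ± 35.3 in DCX- (5.81 ± 1.21, adjusted p = 6.04e-04). The natriuretic peptide gene NPPA (5.09 ± 1.15), PHACTR3 (4.48 ± 0.31), GAD1 (4.47 ± 0.71, adjusted p = 2.03e-05), DLX6-AS1 (4.41 ± 0.67), HMP19 (4.33 ± 0.60) and CALB2 (4.30 ± 0.89) were higher, as were SST (4.92 ± 1.40, adjusted p = 0.0109), DCX (3.85 ± 0.37, adjusted p = 1.46e-09), LHX6 (3.38 ± 0.69, adjusted p = 4.67e-04) and DLX2 (2.14 ± 0.62, adjusted p = 0.0119). Lower in DCX+ were CTGF, a matrix-associated growth factor gene (-4.74 ± 1.09, adjusted p = 0.00171), IGFBP7 (-4.62 ± 1.03), the smooth muscle marker TAGLN (-3.93 ± 1.20), the stress-induced cytokine gene GDF15 (-3.93 ± 0.64), C5orf49 (-3.81 ± 0.78), the chemokine gene CCL2 (-3.79 ± 1.02) and CPXM2 (-3.59 ± 0.30). The small nucleolar RNA gene SNORA18 was listed at 0 in all 5 DCX+ libraries against 14.1 ± 6.595 TPM. SOX2 (-0.41 ± 0.38, adjusted p = 0.509) and NKX2-1 (0.71 ± 1.04, adjusted p = 0.701) did not pass, and MKI67 (-1.14 ± 0.54, adjusted p = 0.138) passed with a replicate block (adjusted p = 0.0392) and in a fit to the compared libraries alone (adjusted p = 0.0143).

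The D100 sort called 3100 genes, 1507 higher and 1593 lower, of which 3077 had the same sign in both batches that hold both fractions, and 3881 without the 4 batch 2 libraries. Leaving out 100P/S DCX- D100 replicate 2 gave 1832, and ended the calls of SST (adjusted p = 0.105), DLX2 (0.153), CCL2 (0.07497) and TAGLN (0.124), those of DLX2 and TAGLN being lost in 2 of the 8 fits that left out 1 library. Oligodendrocyte genes were higher in DCX+ for 7 of 14, MAG at 3.09 ± 0.59 and GPR17 at 3.02 ± 0.73 (adjusted p = 3.68e-05 and adjusted p = 0.184 with an estimated correlation). Astrocyte genes were lower for 9 of 14, AGT at -2.61 ± 0.34 and ALDH1L1 at -2.11 ± 0.37 (adjusted p = 8.86e-06 and adjusted p = 0.0736 with an estimated correlation). Pan-neuronal genes were higher for 15 of 18 (adjusted p = 1.51e-15 and adjusted p = 0.01599 with an estimated correlation). Presynaptic genes were higher for 19 of 22 (adjusted p = 1.33e-18 and adjusted p = 0.01601 with an estimated correlation). Interferon genes were lower for 9 of 17, IFIT1 at -2.69 ± 0.54 (adjusted p = 4.28e-06 and adjusted p = 0.01601 with an estimated correlation).

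The remaining calls at D100 were lost with an estimated correlation. MGE factors had 6 of 15 higher (adjusted p = 0.00364 and adjusted p = 0.164 with an estimated correlation). GABA synthesis had 4 of 8 higher, SLC32A1 at 4.26 ± 0.53 (adjusted p = 0.00436 and adjusted p = 0.189 with an estimated correlation). Interneuron subtype had 9 of 26 higher (adjusted p = 2.71e-04 and adjusted p = 0.208 with an estimated correlation). GABA and glycine receptors had 11 of 18 higher (adjusted p = 6.76e-08 and adjusted p = 0.0736 with an estimated correlation), glutamate receptors 10 of 19 (adjusted p = 5.51e-07 and adjusted p = 0.122 with an estimated correlation). Channels had 7 of 21 higher (adjusted p = 2.83e-06 and adjusted p = 0.0807 with an estimated correlation). Radial glia had 9 of 20 lower (adjusted p = 1.48e-05 and adjusted p = 0.122 with an estimated correlation). Cell cycle had 5 of 22 lower, and 15 adjusted over the list alone (adjusted p = 8.86e-06 and adjusted p = 0.307 with an estimated correlation). Mesenchymal genes had 7 of 12 lower, with THY1 higher at 2.83 ± 0.37 (adjusted p = 0.00177 and adjusted p = 0.184 with an estimated correlation). Unfolded protein and amino acid stress had 6 of 18 lower (adjusted p = 0.00801 and adjusted p = 0.307 with an estimated correlation). Cholesterol synthesis had 5 of 20 lower (adjusted p = 0.002304 and adjusted p = 0.375 with an estimated correlation).

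**Figure D2:**
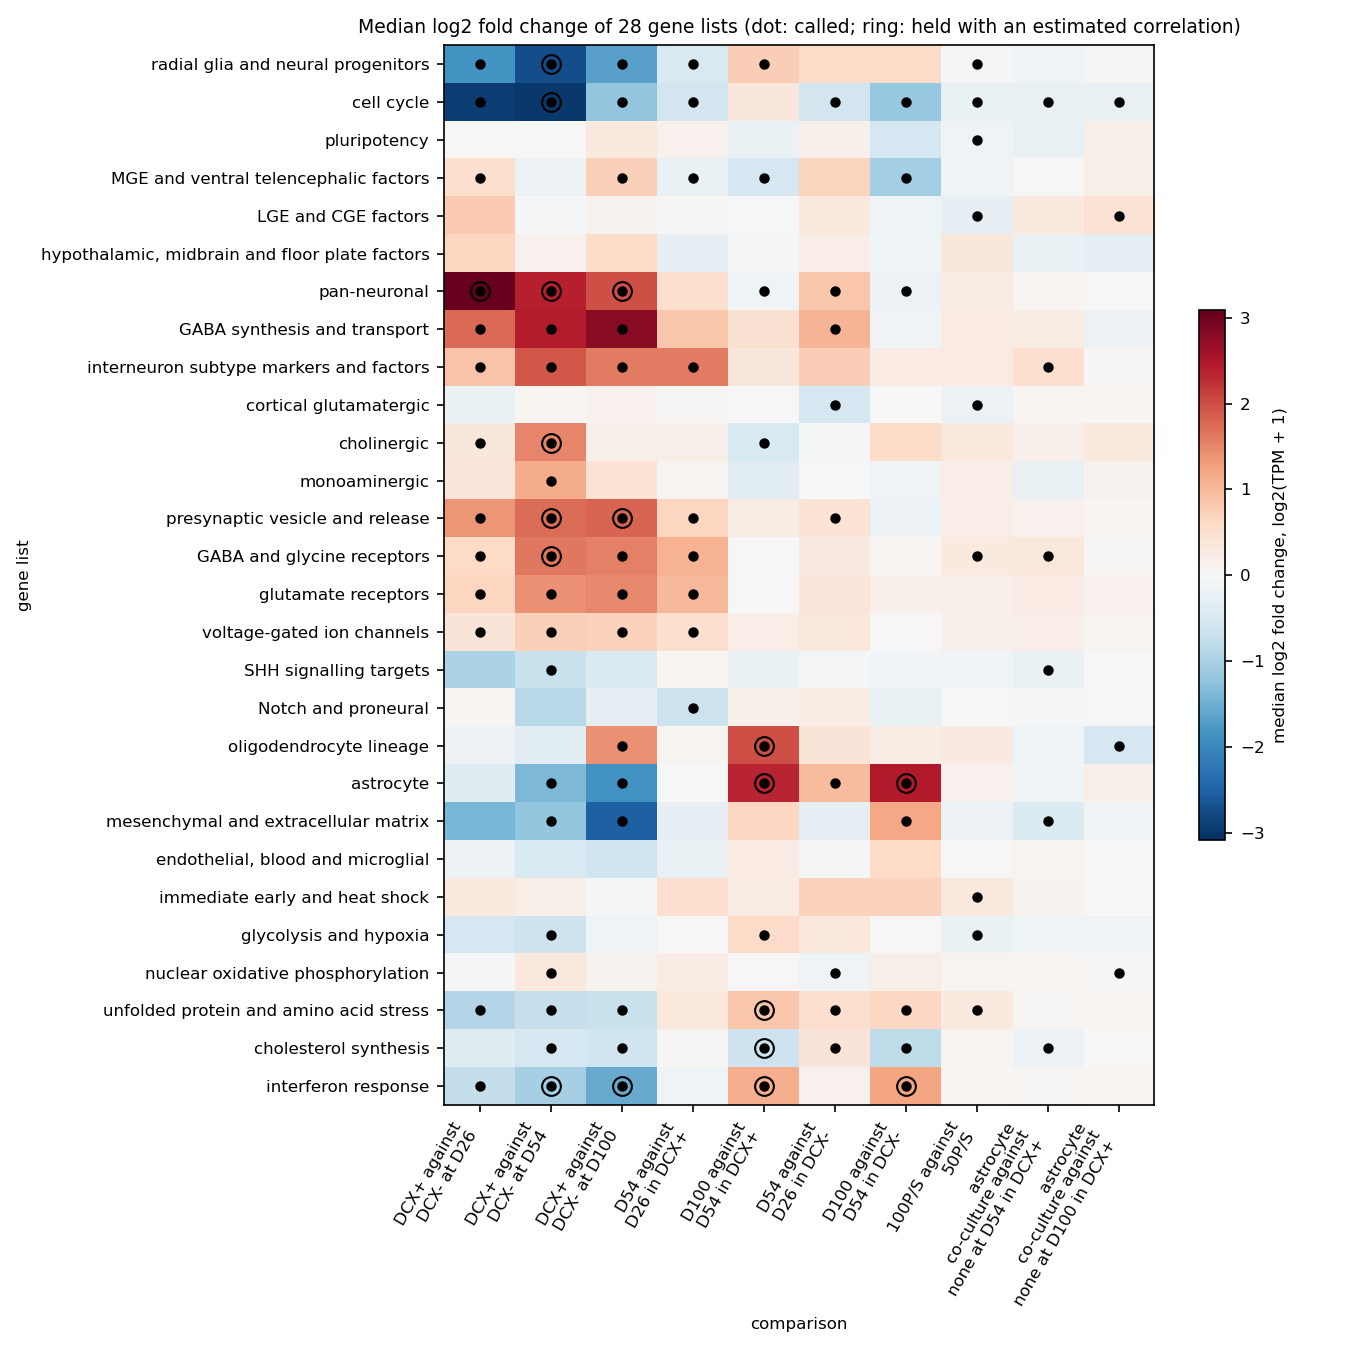
Median log2 fold change (colour) of each of 28 gene lists in the 10 comparisons, with a filled dot where the list was called by camera and a ring where the call also held with an estimated correlation. Pan-neuronal genes have medians of 3.09, 2.41 and 1.98 in the sort comparisons at D26, D54 and D100, and cell cycle genes -2.94, -2.98 and -1.22.

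Maturation was read within DCX+ cells without astrocytes, with D54 against D26 (7 against 5 libraries) as the earlier step. NPY, a neuropeptide gene, rose by 5.42 ± 1.39, adjusted p = 0.0157, SST by 4.38 ± 1.13, adjusted p = 0.01596, from 2991 ± 6520.3 to 10756 ± 7592 TPM, and CALB2 by 3.64 ± 0.71, adjusted p = 0.003003. The phosphodiesterase gene PDE1A (5.01 ± 1.01, adjusted p = 0.00377), the matrix gene NPNT (4.31 ± 0.67, adjusted p = 6.98e-04), NPPA (3.30 ± 0.93, adjusted p = 0.0275) and the GABA receptor subunit genes GABRA2 (3.76 ± 0.69, adjusted p = 0.00189) and GABRB1 (3.46 ± 0.41, adjusted p = 5.51e-06) rose too. MFNG, a modifier of Notch (-3.02 ± 0.63, adjusted p = 0.004596), IFITM2 (-2.58 ± 0.74), SERPINF1 (-2.53 ± 0.75), the carbonic anhydrase gene CA14 (-2.43 ± 0.57), S100A13 (-2.36 ± 0.61), IGDCC3 (-2.34 ± 0.54), NKAIN4 (-2.26 ± 0.51) and CMTM7 (-2.11 ± 0.63) fell. Without the 4 batch 2 libraries the changes were larger, with NPY at 8.42 ± 0.94, adjusted p = 4.50e-08, SST at 6.98 ± 0.65, adjusted p = 1.29e-09 (from 75.2 ± 45.6 to 12532 ± 6533 TPM), PDE1A at 7.47 ± 0.55, GABRA2 at 5.33 ± 0.42 and MFNG at -4.15 ± 0.53. Within batch 2 the D54 to D26 difference of NPY was 0.04, against 8.02 in batch 1 and 8.48 in batch 3. DCX (0.19 ± 0.30, adjusted p = 0.774), LHX6 (-0.49 ± 0.55, adjusted p = 0.668), DLX2 (-0.08 ± 0.50, adjusted p = 0.949), SOX2 (0.60 ± 0.31, adjusted p = 0.254), MKI67 (-0.12 ± 0.43, adjusted p = 0.917) and NKX2-1 (0.06 ± 0.84, adjusted p = 0.981) did not pass. GAD1 (1.77 ± 0.58, adjusted p = 0.0583) passed without the 4 libraries (2.60 ± 0.53, adjusted p = 4.76e-04).

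The labels gave 919 changed genes, 709 risen and 210 fallen, 803 of them with the same sign in all 3 batches. Leaving out the 4 libraries gave 3519, 2038 risen and 1481 fallen, with 885 called in both. A fit to the compared libraries alone called 0 genes by limma, with 2369 at an unadjusted p under 0.05. The share risen, 77.1%, was 63.6% with median-of-ratios scaling and 57.5% after quantile normalization. Leaving out 1 library moved the count from 473 without 50P/S DCX+ D54 replicate 3 to 1848 without 100P/S DCX+ D26 replicate 2, 1 of the 4. Of the 12 fits that left out 1 library, NPPA, SERPINF1 and IFITM2 lost their calls in 9 and CMTM7 in 8. These 4 calls, weak by the labels, held without the 4 libraries. SST lost its call in 3 fits, and NPY and S100A13 in 2. The highest adjusted p-values came without 50P/S DCX+ D26 replicate 2 for NPY (adjusted p = 0.0524), CMTM7 (0.146), S100A13 (0.0654) and IFITM2 (0.1001). They came without 50P/S DCX+ D26 replicate 1 for SERPINF1 (0.112), and without 100P/S DCX+ D26 replicate 3 for SST (0.0576) and NPPA (0.0822). A replicate block ended the calls of NPPA (adjusted p = 0.0636), CMTM7 (0.0782), SERPINF1 (0.0698) and IFITM2 (0.0771).

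Interneuron subtype genes rose for 11 of 26, ERBB4 among them (2.89 ± 0.71), and for 13 adjusted over the list alone (adjusted p = 1.74e-06 and adjusted p = 0.242 with an estimated correlation). GABA and glycine receptors rose for 8 of 18 (adjusted p = 6.71e-10 and adjusted p = 0.134 with an estimated correlation). Glutamate receptors rose for 8 of 19, GRIN2B at 2.39 ± 0.44 (adjusted p = 1.45e-05 and adjusted p = 0.391 with an estimated correlation). Presynaptic genes rose for 6 of 22, SYP at 1.20 ± 0.26 (adjusted p = 9.60e-05 and adjusted p = 0.437 with an estimated correlation). Channels rose for 5 of 21, SCN2A at 1.84 ± 0.35 (adjusted p = 7.02e-04 and adjusted p = 0.391 with an estimated correlation). Notch and proneural genes fell for 2 of 12, DLL1 at -1.65 ± 0.35 (adjusted p = 3.38e-04 and adjusted p = 0.165 with an estimated correlation). Radial glia fell for 1 of 20, HMGA2 at -1.62 ± 0.38 (adjusted p = 0.00437 and adjusted p = 0.437 with an estimated correlation), and the cell cycle list was called downwards with 1 of 22 fallen (adjusted p = 1.00e-05 and adjusted p = 0.461 with an estimated correlation). MGE factors were called downwards with 0 of 15 past the threshold (adjusted p = 0.0433 and adjusted p = 0.437 with an estimated correlation), a call lost without the 4 libraries (adjusted p = 0.165), with median-of-ratios scaling (0.0832) and after quantile normalization (0.135). Without the 4 the interneuron, GABA receptor, glutamate receptor and Notch lists held with an estimated correlation, each at adjusted p = 0.04097.

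**Figure D3:**
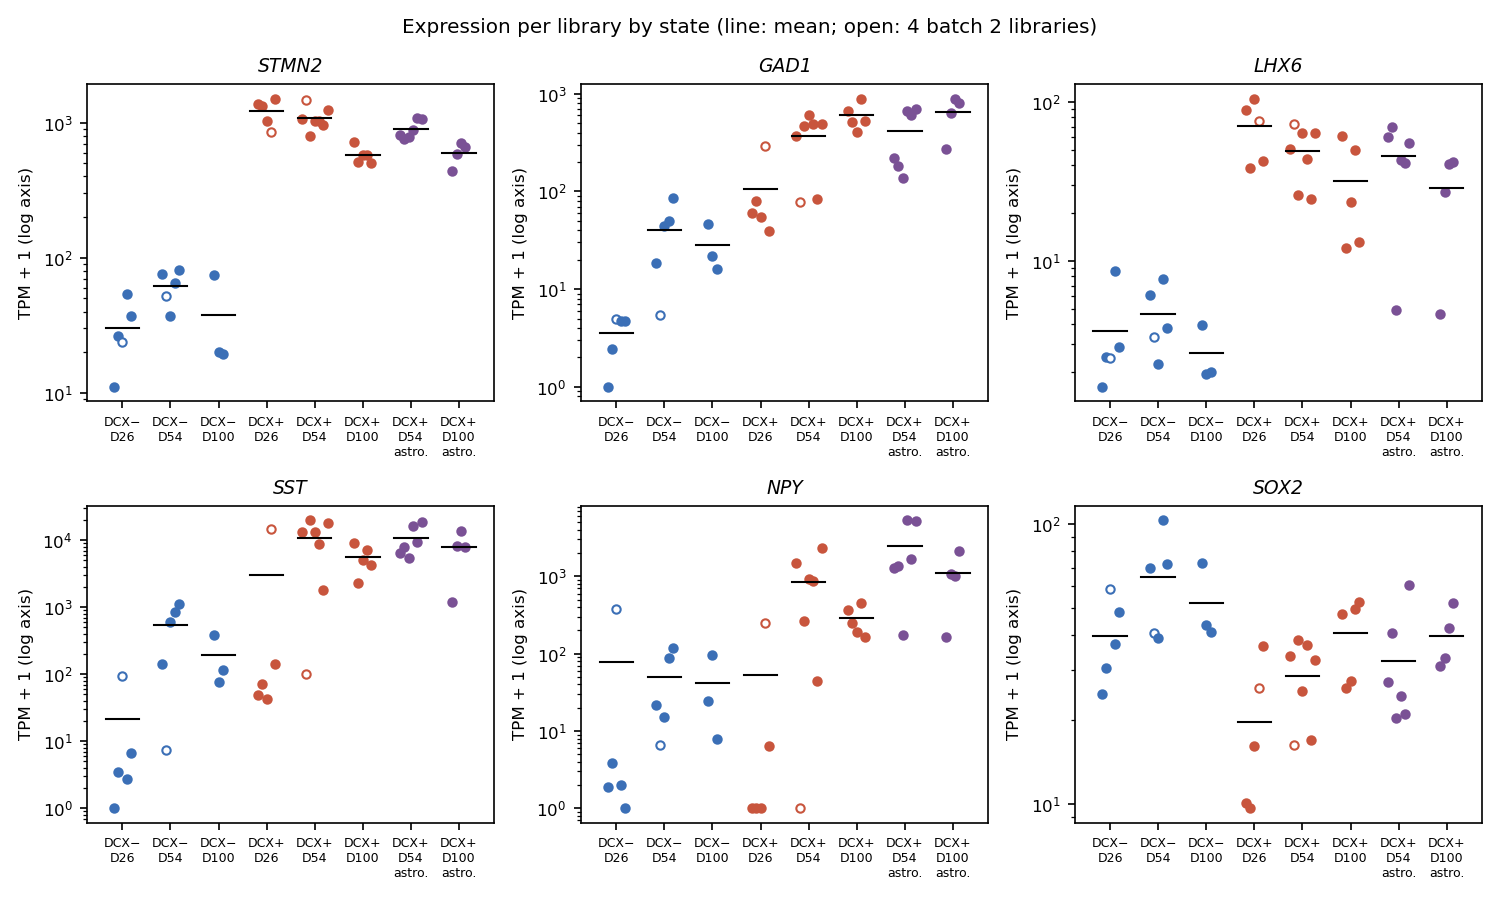
TPM (log axis of TPM + 1) of STMN2, GAD1, LHX6, SST, NPY and SOX2 in each library by state, with bars at the state mean and open symbols for the 4 batch 2 libraries whose day score disagrees with the label. SST has a mean of 10756 ± 7592 TPM in DCX+ at D54 and 2991 ± 6520.3 TPM at D26, where the open symbol of 100P/S DCX+ D26 stands at 14655 TPM.

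From D54 to D100 (7 and 5 libraries), glial transcripts rose in DCX+ cells. GFAP, the astrocyte filament gene, rose from 0.130000 ± 0.177 to 100.2 ± 118 TPM (5.65 ± 0.72, adjusted p = 1.92e-06), and the water channel gene AQP4 from 0.841 ± 0.793 to 111 ± 89.8 TPM (5.60 ± 0.59, adjusted p = 7.89e-08). MBP, a myelin gene, rose by 4.72 ± 0.65, adjusted p = 6.66e-06, with the tetraspanin gene CD9 (5.36 ± 0.55, adjusted p = 6.27e-08), HEPN1 (5.25 ± 0.70), NDUFA4L2 (5.09 ± 0.68), SLC1A3 (4.89 ± 0.78) and the prostaglandin synthase gene PTGDS (4.87 ± 0.53). Genes that fell were GSG1 (-2.37 ± 0.37, adjusted p = 6.38e-05), the transcription factor gene BCL11A (-1.94 ± 0.43, adjusted p = 0.00411), the RNA-binding protein gene IGF2BP1 (-1.74 ± 0.34), DCC (-1.74 ± 0.39), PHF21B (-1.72 ± 0.41), RUNX1T1 (-1.68 ± 0.36) and EDARADD (-1.65 ± 0.50, adjusted p = 0.0435). Of the fixed markers DCX (-0.09 ± 0.30, adjusted p = 0.918), GAD1 (1.10 ± 0.58, adjusted p = 0.314), SST (0.28 ± 1.13, adjusted p = 0.935), LHX6 (-0.85 ± 0.55, adjusted p = 0.457), DLX2 (-0.56 ± 0.50, adjusted p = 0.615), NKX2-1 (-0.70 ± 0.84, adjusted p = 0.737), SOX2 (0.59 ± 0.31, adjusted p = 0.314) and MKI67 (0.30 ± 0.43, adjusted p = 0.788) did not pass.

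This step changed 885 genes, 763 up and 122 down. The sign was the same in all 3 batches for 847, and 1187 changed without the 4 libraries. The share risen, 86.2%, was 73.3% with median-of-ratios scaling and 62.5% after quantile normalization. Leaving out 50P/S DCX+ D100 replicate 3 gave 556 genes. The call of EDARADD was lost in 8 of 12 fits that left out 1 library, with the highest adjusted p (0.171) without 100P/S DCX+ D100 replicate 3, and with a replicate block (0.0506).

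Oligodendrocyte genes rose for 10 of 14 (adjusted p = 8.67e-18 and adjusted p = 0.00544 with an estimated correlation). MAG among them was listed at 0 in all 7 D54 libraries and stood at 22.5 ± 22.8 TPM at D100. Astrocyte genes rose for 9 of 14, AGT at 3.41 ± 0.27 (adjusted p = 1.76e-16 and adjusted p = 7.97e-04 with an estimated correlation). Interferon genes rose for 9 of 17, B2M at 2.53 ± 0.32 (adjusted p = 3.45e-09 and adjusted p = 0.00204 with an estimated correlation). Unfolded protein and amino acid stress genes rose for 9 of 18, DDIT3 at 1.94 ± 0.35 (adjusted p = 3.45e-09 and adjusted p = 0.0312 with an estimated correlation). Cholesterol synthesis fell for 8 of 20, FDFT1 at -1.24 ± 0.19 (adjusted p = 1.69e-17 and adjusted p = 0.0264 with an estimated correlation). Radial glia genes rose for 8 of 20 (adjusted p = 5.88e-05 and adjusted p = 0.169 with an estimated correlation). Of these, HOPX (4.21 ± 0.79), TNC (3.71 ± 0.63), FABP7 (2.63 ± 0.49) and SLC1A3 are also made by astrocytes. Glycolysis and hypoxia genes rose for 5 of 20, ADM at 4.20 ± 0.49 and CA9 at 3.14 ± 0.42 (adjusted p = 2.19e-06 and adjusted p = 0.206 with an estimated correlation). Pan-neuronal genes were called downwards, with 3 of 18 fallen, TUBB3 at -1.17 ± 0.16 and STMN1 at -0.85 ± 0.16 (adjusted p = 0.00183 and adjusted p = 0.282 with an estimated correlation). MGE factors (adjusted p = 0.0378 and adjusted p = 0.282 with an estimated correlation) and cholinergic genes (adjusted p = 0.024001 and adjusted p = 0.0876 with an estimated correlation) were called downwards with 0 members past the threshold. With median-of-ratios scaling the MGE and cholinergic calls were lost (adjusted p = 0.0764 and 0.0685). After quantile normalization the MGE, cholinergic and pan-neuronal calls were lost (adjusted p = 0.173, 0.0963 and 0.0538).

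In DCX- libraries, where carry-over of neurons was not tested, SST rose from 20.8 ± 41.01 TPM at D26 to 543 ± 466 at D54 (5 each, 5.32 ± 1.21, adjusted p = 0.0143). C1orf61 (4.88 ± 1.15, adjusted p = 0.0189), the matrix proteoglycan gene BCAN (4.75 ± 1.04, adjusted p = 0.0113), PMP2 (4.72 ± 0.89, adjusted p = 0.00351), the astroglial matrix gene SPARCL1 (4.67 ± 0.88, adjusted p = 0.00351), FIBIN (4.27 ± 0.77), the hyaluronan synthase gene HAS2 (3.82 ± 0.73) and IL13RA2 (3.75 ± 0.67) rose with it, as did GAD1 (3.21 ± 0.62, adjusted p = 0.00413). The collagen gene COL2A1 (-3.48 ± 0.73, adjusted p = 0.00812), RARRES2 (-2.84 ± 0.80), LIN28A, an RNA-binding protein gene of early cells (-2.66 ± 0.67, adjusted p = 0.0269), S100A4 (-2.40 ± 0.67), CRYBA1 (-2.29 ± 0.56), CLEC18A (-2.17 ± 0.60) and SYNGR3 (-2.0 ± 0.49) fell. The small nucleolar RNA gene SNORD8 was listed at 0 in all D54 libraries against 5.404 ± 4.94 TPM at D26. Without the 4 batch 2 libraries SST rose by 7.43 ± 0.69, adjusted p = 1.26e-09 (from 2.46 ± 2.38 to 677 ± 412 TPM), BCAN by 7.34 ± 0.72, and LIN28A fell with -4.20 ± 0.31, adjusted p = 1.08e-11. Within batch 2 the differences of BCAN and LIN28A were 0.68 and -0.21. DCX (0.65 ± 0.32, adjusted p = 0.303), DLX2 (1.0 ± 0.53, adjusted p = 0.348), SOX2 (0.68 ± 0.33, adjusted p = 0.294), NKX2-1 (0.92 ± 0.90, adjusted p = 0.662), LHX6 (0.49 ± 0.59, adjusted p = 0.743) and MKI67 (0.25 ± 0.47, adjusted p = 0.845) did not pass, DCX and DLX2 doing so without the 4 libraries (1.25 ± 0.30, adjusted p = 0.00319, and 1.98 ± 0.48, adjusted p = 0.00348).

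Here 389 genes changed by the labels, 334 up and 55 down, 371 of them with the same sign in all 3 batches. Without the 4 libraries 2698 changed, 2054 up and 644 down, with all 389 called in both. A fit to the compared libraries alone called 0 by limma, with 2397 at an unadjusted p under 0.05. The share risen, 85.9%, was 63.4% with median-of-ratios scaling and 64.7% after quantile normalization. Leaving out 1 library gave from 68 genes, without 100P/S DCX- D54 replicate 3, to 1188, without 50P/S DCX- D54 replicate 2, 1 of the 4. Of the 10 fits that left out 1 library, CLEC18A, CRYBA1, S100A4, LIN28A, SYNGR3 and RARRES2 lost their call in 8 and C1orf61 in 6. These 7 calls, weak by the labels, held without the 4. SST lost its call in 3 fits, BCAN in 2 and COL2A1 in 1. The highest adjusted p-values came without 50P/S DCX- D54 replicate 3 for SST, C1orf61 and BCAN (adjusted p = 0.0747, 0.0843 and 0.0619), CLEC18A (0.168), CRYBA1 (0.0951), S100A4 (0.168) and LIN28A (0.114). They came without 100P/S DCX- D54 replicate 3 for SYNGR3 (0.118) and COL2A1 (0.0523), and without 100P/S DCX- D54 replicate 2 for RARRES2 (0.178). A replicate block ended the calls of S100A4 (adjusted p = 0.0512) and RARRES2 (0.0518).

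Astrocyte genes rose in DCX- from D26 to D54 for 3 of 14, S100B at 3.29 ± 0.65 (adjusted p = 0.00451 and adjusted p = 0.432 with an estimated correlation). Pan-neuronal genes rose for 3 of 18 (adjusted p = 0.002398 and adjusted p = 0.432 with an estimated correlation). Presynaptic genes rose for 2 of 22, SYP at 1.45 ± 0.28 (adjusted p = 0.002398 and adjusted p = 0.525 with an estimated correlation). GABA synthesis genes rose for 2 of 8 (adjusted p = 0.0178 and adjusted p = 0.432 with an estimated correlation), and unfolded protein and amino acid stress genes for 2 of 18, CALR at 1.0 ± 0.18 (adjusted p = 0.00156 and adjusted p = 0.432 with an estimated correlation). The following lists were called with 0 members past the threshold. Cell cycle (adjusted p = 4.00e-07 and adjusted p = 0.432 with an estimated correlation) and cortical glutamatergic genes (adjusted p = 0.0356 and adjusted p = 0.432 with an estimated correlation) were called downwards. Oxidative phosphorylation was called downwards as well (adjusted p = 0.00262 and adjusted p = 0.432 with an estimated correlation). Cholesterol synthesis was called upwards (adjusted p = 0.0456 and adjusted p = 0.604 with an estimated correlation), but not with a replicate block (adjusted p = 0.05601). Median-of-ratios scaling ended the glutamatergic and cholesterol calls (adjusted p = 0.0828 and 0.0722), and quantile normalization that of oxidative phosphorylation (0.0681).

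From D54 to D100 (5 and 3 libraries) astrocyte genes rose in DCX- cells. GFAP rose from 1.60000 ± 1.903 to 245 ± 178 TPM (6.49 ± 0.89, adjusted p = 3.60e-06), AQP4 by 6.01 ± 0.74, adjusted p = 4.65e-07, AGT, which astrocytes express, by 5.92 ± 0.34, adjusted p = 2.65e-15, and PTGDS by 5.64 ± 0.66, adjusted p = 1.70e-07. The chaperone gene CRYAB (5.24 ± 0.84), CAPS (5.03 ± 0.54), GPNMB (5.0 ± 0.49) and GDF15 (4.84 ± 0.64) rose too. HES5, a Notch effector of progenitors (-2.87 ± 0.62, adjusted p = 0.00205), BCL11A (-2.88 ± 0.54, adjusted p = 4.10e-04), HELT (-2.97 ± 0.58), PLA2G3 (-2.91 ± 0.67), SHISA2 (-2.73 ± 0.85), HIST1H2BH (-2.85 ± 0.88) and SCARNA22 (-4.03 ± 0.96) fell. SNORA12 was listed at 0 at D100 against 9.07 ± 3.05 TPM. TTR, a choroid plexus gene below the filter and chosen after its values were seen, stood at 397 and 42.48 TPM in the 50P/S and 100P/S DCX- D100 libraries of batch 2. It was listed at 0 in the third and in all DCX- libraries at D26 and D54, so another cell type than astrocytes is not excluded there. NKX2-1 (-2.18 ± 1.04, adjusted p = 0.246), DLX2 (-1.50 ± 0.62, adjusted p = 0.159), DCX (-0.97 ± 0.37, adjusted p = 0.126), LHX6 (-0.77 ± 0.69, adjusted p = 0.623), MKI67 (-0.74 ± 0.54, adjusted p = 0.514), SST (-0.45 ± 1.40, adjusted p = 0.915), SOX2 (-0.23 ± 0.38, adjusted p = 0.824) and GAD1 (-0.12 ± 0.71, adjusted p = 0.959) did not pass, DCX and DLX2 doing so without the 4 libraries (-1.28 ± 0.32, adjusted p = 0.00995, and -1.78 ± 0.52, adjusted p = 0.0273).

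The step changed 1031 genes, 727 up and 304 down. The sign was the same in both batches that hold both days for 1023, and 1135 changed without the 4 libraries. The share risen, 70.5%, was 49.8% after quantile normalization. Leaving out 100P/S DCX- D100 replicate 2 gave 568 genes and ended the calls of PLA2G3 (adjusted p = 0.0703), SCARNA22 (0.0697) and the cell cycle gene MCM3 (0.0504). Of the 8 fits that left out 1 library, SHISA2 and HIST1H2BH lost their calls in 6, SNORA12 and SCARNA22 in 2 and PLA2G3 and MCM3 in 1. The highest adjusted p came without 50P/S DCX- D100 replicate 2 for HIST1H2BH (0.319) and SNORA12 (0.0806), and without 50P/S DCX- D54 replicate 2 for SHISA2 (0.151), whose call a replicate block also ended (0.0592). HIST1H2BH was not called without the 4 libraries either (adjusted p = 0.0749).

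Astrocyte genes rose from D54 to D100 for 8 of 14, CD44 at 4.40 ± 0.52 (adjusted p = 2.56e-14 and adjusted p = 0.00171 with an estimated correlation). Interferon genes rose for 6 of 17, IFIT2 at 3.36 ± 0.51 (adjusted p = 4.56e-08 and adjusted p = 0.00434 with an estimated correlation). Unfolded protein and amino acid stress genes rose for 3 of 18, DDIT3 at 2.62 ± 0.43 (adjusted p = 4.95e-04 and adjusted p = 0.2898 with an estimated correlation). Cell cycle genes fell for 6 of 22, MCM3 at -1.48 ± 0.36 (adjusted p = 1.61e-10 and adjusted p = 0.2898 with an estimated correlation). The MGE list was called downwards (adjusted p = 1.32e-04 and adjusted p = 0.0961 with an estimated correlation). Cholesterol synthesis fell for 9 of 20, FDFT1 at -1.22 ± 0.24 (adjusted p = 4.06e-10 and adjusted p = 0.181 with an estimated correlation). Pan-neuronal genes were called downwards with 3 of 18 fallen, TUBB3 at -1.35 ± 0.20 (adjusted p = 0.0416 and adjusted p = 0.508 with an estimated correlation). Mesenchymal genes were called upwards with 2 of 12 risen (adjusted p = 0.0398 and adjusted p = 0.438 with an estimated correlation). A replicate block ended the pan-neuronal and mesenchymal calls (adjusted p = 0.129 and 0.128). The former was also lost after quantile normalization (adjusted p = 0.0921).

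Whether the fractions changed differently from D26 to D100 was tested as a difference of their changes. It passed for 333 genes, 194 with a positive difference (the more upward change in DCX+) and 139 with a negative one. The catenin gene CTNNA2 (-2.61 ± 0.34, adjusted p = 2.09e-05), SEMA4A (-3.91 ± 0.57) and the complement gene C4B (-2.18 ± 0.33) had negative differences. The transporter gene SLC7A3 (2.77 ± 0.43, adjusted p = 3.37e-04), the polyamine enzyme gene AMD1 (1.69 ± 0.27) and the oligodendrocyte gene ENPP6 (1.95 ± 0.53, adjusted p = 0.0419) had positive ones. CPXM2, a carboxypeptidase family gene (adjusted p = 1.05e-06), and AGT (adjusted p = 0.00101) passed with a negative difference and MAG (adjusted p = 0.0247) with a positive one, but all 3 were listed at 0 in every D26 library of both fractions. GFAP, listed at 0 in every DCX- D26 library, did not pass (adjusted p = 0.368). These genes were chosen after their values were seen. Among lists 3 were called. Cell cycle genes were positive for 3 of 22, MCM6 at 1.98 ± 0.40 among them, and for 13 adjusted over the list alone (adjusted p = 3.17e-11 and adjusted p = 0.431 with an estimated correlation). Oligodendrocyte genes were positive for 2 of 14 (adjusted p = 4.22e-07 and adjusted p = 0.342 with an estimated correlation). Astrocyte genes were negative for 2 of 14 (adjusted p = 6.89e-05 and adjusted p = 0.342 with an estimated correlation). Without the 4 libraries 898 genes passed, 319 of them in both. A fit to the compared libraries alone gave 141. Leaving out 100P/S DCX- D100 replicate 2 gave 119 and leaving out 100P/S DCX+ D26 replicate 2 gave 531.

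**Figure D4:**
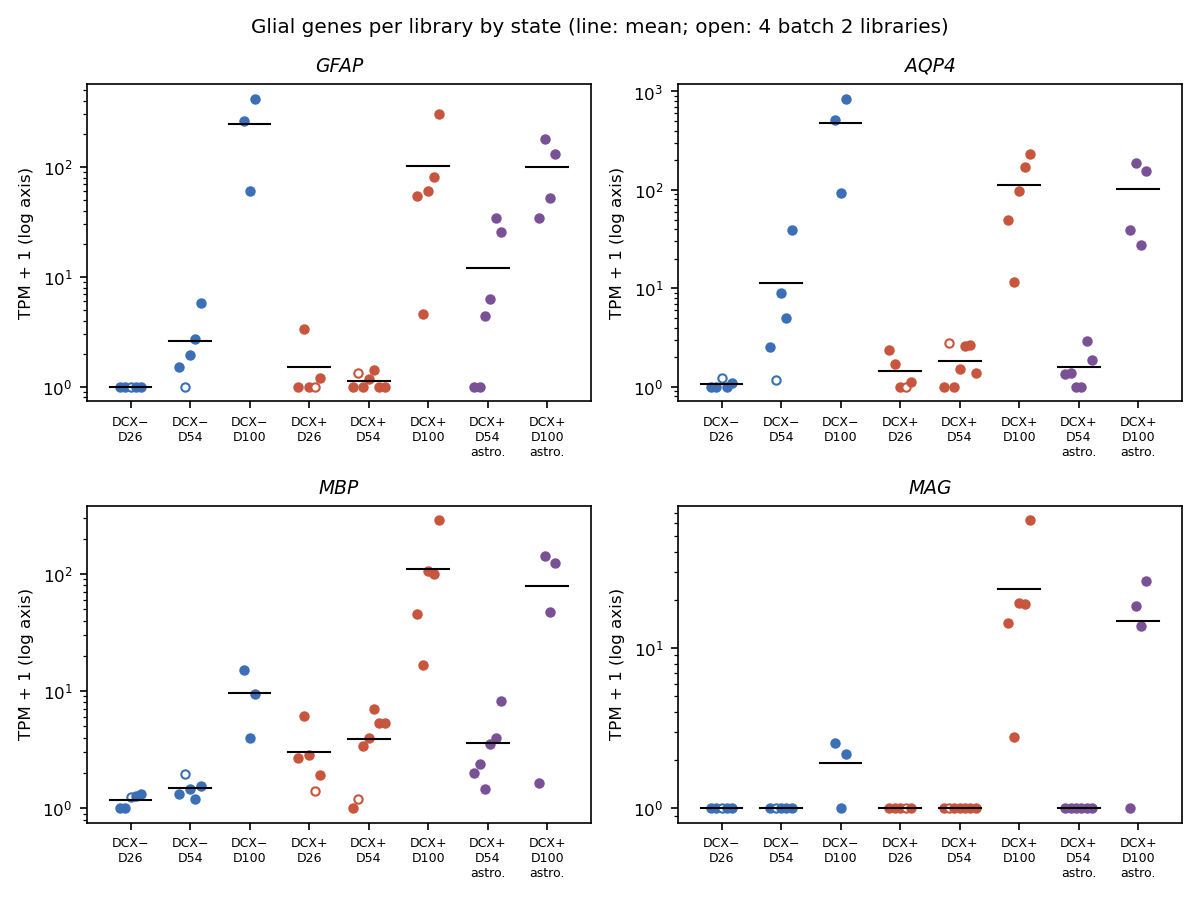
TPM (log axis of TPM + 1) of GFAP, AQP4, MBP and MAG in each library by state, with bars at the state mean. At D100, MBP stands at 109.7 ± 105 TPM in DCX+ without astrocytes and at 8.57 ± 5.61 TPM in DCX-, while AQP4 stands at 111 ± 89.8 and 481 ± 374 TPM.

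The labels 100P/S and 50P/S were compared within states (18 against 22 libraries). FRZB, a secreted WNT antagonist gene (2.18 ± 0.53, adjusted p = 0.0368), SPARCL1 (1.93 ± 0.44, adjusted p = 0.0239), IL13RA2 (1.75 ± 0.34, adjusted p = 0.008702), the receptor gene GPR83 (1.68 ± 0.40, adjusted p = 0.0285), C5orf49 (1.59 ± 0.34), FIBIN (1.55 ± 0.39), the synuclein gene SNCG (1.52 ± 0.40) and the NODAL co-receptor gene CFC1 (1.40 ± 0.31, adjusted p = 0.0197) were higher with 100P/S. The secretagogin gene SCGN (-2.28 ± 0.44, adjusted p = 0.00778), the homeobox gene POU3F4 (-2.21 ± 0.48, adjusted p = 0.0197), THSD7B (-1.17 ± 0.23), the ephrin receptor gene EPHA3 (-1.15 ± 0.30), C8orf4 (-1.08 ± 0.27), RGS20 (-0.99 ± 0.19, adjusted p = 0.00667), the neuronal RNA-binding gene ELAVL4 (-0.82 ± 0.19) and SCML2 (-0.77 ± 0.17) were lower. Fixed markers did not pass. NKX2-1 was at 0.59 ± 0.46, adjusted p = 0.527, with 0.93 ± 0.20 outside batch 2 and 0.75 ± 0.69 in it. Others were SST at 1.91 ± 0.62, LHX6 at -0.14 ± 0.30, GAD1 at 0.54 ± 0.31, DLX2 at -0.18 ± 0.27, DCX at -0.24 ± 0.16, SOX2 at 0.40 ± 0.17 and MKI67 at 0.17 ± 0.24 (adjusted p = 0.108, 0.859, 0.379, 0.779, 0.4603, 0.2104 and 0.761).

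In total, 165 genes differed, 136 higher and 29 lower with 100P/S, and 148 had the same sign in the 3 batches that hold both labels. Without the 4 libraries 366 differed, with 109 in both sets. Within DCX+ without astrocytes, DCX- and co-culture libraries taken alone limma called 0, with 1219, 1994 and 925 genes at an unadjusted p under 0.05. The share higher, 82.4%, was 54.9% with median-of-ratios scaling and 47.0% after quantile normalization. Leaving out 1 library gave from 75 genes without 100P/S DCX- D54 replicate 3 to 249 without 50P/S DCX+ D54 replicate 3. Libraries of both fractions with the same number, day and label may share a culture, which makes 27 cultures (13 with 100P/S), and with this as a random term, a setting chosen after the data were seen, 77 genes were called. That term ended the calls of FIBIN, SNCG, C8orf4 and EPHA3. Of the 40 fits that left out 1 library, EPHA3 lost its call in 30, SNCG in 27, FIBIN in 21, C8orf4 in 14, FRZB in 12 and GPR83 in 3. SPARCL1 and ELAVL4 lost theirs in 1. The highest adjusted p-values came without 100P/S DCX- D54 replicate 3 for SPARCL1 (adjusted p = 0.05195), GPR83 (0.0586), FIBIN (0.0855) and SNCG (0.0872). They came without 100P/S DCX- D100 replicate 2 for FRZB (0.0789), ELAVL4 (0.0584) and EPHA3 (0.0973), and without 100P/S DCX+ D100 replicate 3 for C8orf4 (0.0624).

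LGE and CGE factors were called lower with 100P/S for 2 of 13, SP8 at -1.33 ± 0.28 and SCGN (adjusted p = 3.92e-04 and adjusted p = 0.1997 with an estimated correlation). SP8 leaned on batch 2, with -2.33 there and -0.62 in the other batches taken alone. Further lists were called downwards with 0 members past the threshold. They were radial glia (adjusted p = 0.00533 and adjusted p = 0.529 with an estimated correlation) and cell cycle (adjusted p = 1.02e-05 and adjusted p = 0.529 with an estimated correlation). Glycolysis (adjusted p = 6.82e-04 and adjusted p = 0.529 with an estimated correlation) and pluripotency (adjusted p = 0.0149 and adjusted p = 0.243 with an estimated correlation) were others. Cortical glutamatergic genes completed them (adjusted p = 0.00569 and adjusted p = 0.176 with an estimated correlation). Unfolded protein and amino acid stress genes were higher for 2 of 18, CALR at 0.43 ± 0.09, and for 11 adjusted over the list alone (adjusted p = 1.97e-04 and adjusted p = 0.319 with an estimated correlation). GABA and glycine receptors were called upwards with 1 of 18 higher (adjusted p = 0.0229 and adjusted p = 0.6101 with an estimated correlation). Immediate early genes were called upwards with 0 of 16 higher (adjusted p = 0.0435 and adjusted p = 0.6101 with an estimated correlation). Without the 4 libraries the pluripotency, glutamatergic, GABA receptor and immediate early calls were lost (adjusted p = 0.115, 0.102, 0.456 and 0.115). The last was also lost with a replicate block (adjusted p = 0.125). Glycolysis lost its call after quantile normalization (adjusted p = 0.05196).

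Whether the P/S difference depended on the fraction was tested as well. By limma 0 genes passed for a difference between DCX+ and DCX-, with 1066 at an unadjusted p under 0.05, and 0 without the 4 libraries, with 716. The lowest adjusted p, 0.0848, was that of FSTL5 (-2.46 ± 0.46). Among lists 7 were called, all with 0 members past the threshold. Cortical glutamatergic genes were called upwards (median 0.28, adjusted p = 0.00108 and adjusted p = 0.0286 with an estimated correlation). Cell cycle (adjusted p = 4.90e-05 and adjusted p = 0.605 with an estimated correlation) and oligodendrocyte genes (adjusted p = 9.87e-04 and adjusted p = 0.505 with an estimated correlation) were also called upwards. So were glycolysis (adjusted p = 0.00400005 and adjusted p = 0.663 with an estimated correlation) and oxidative phosphorylation (adjusted p = 9.87e-04 and adjusted p = 0.382 with an estimated correlation), the latter not without the 4 libraries (adjusted p = 0.141). Presynaptic genes were called upwards (adjusted p = 0.0277 and adjusted p = 0.849 with an estimated correlation), but not with a replicate block (adjusted p = 0.0766) nor without the 4 libraries (adjusted p = 0.0816). LGE and CGE factors were called downwards (adjusted p = 0.0182 and adjusted p = 0.382 with an estimated correlation). The presynaptic call was also lost with median-of-ratios scaling (adjusted p = 0.148) and after quantile normalization (0.0516), as was that of glycolysis after the latter (0.0518).

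**Figure D5:**
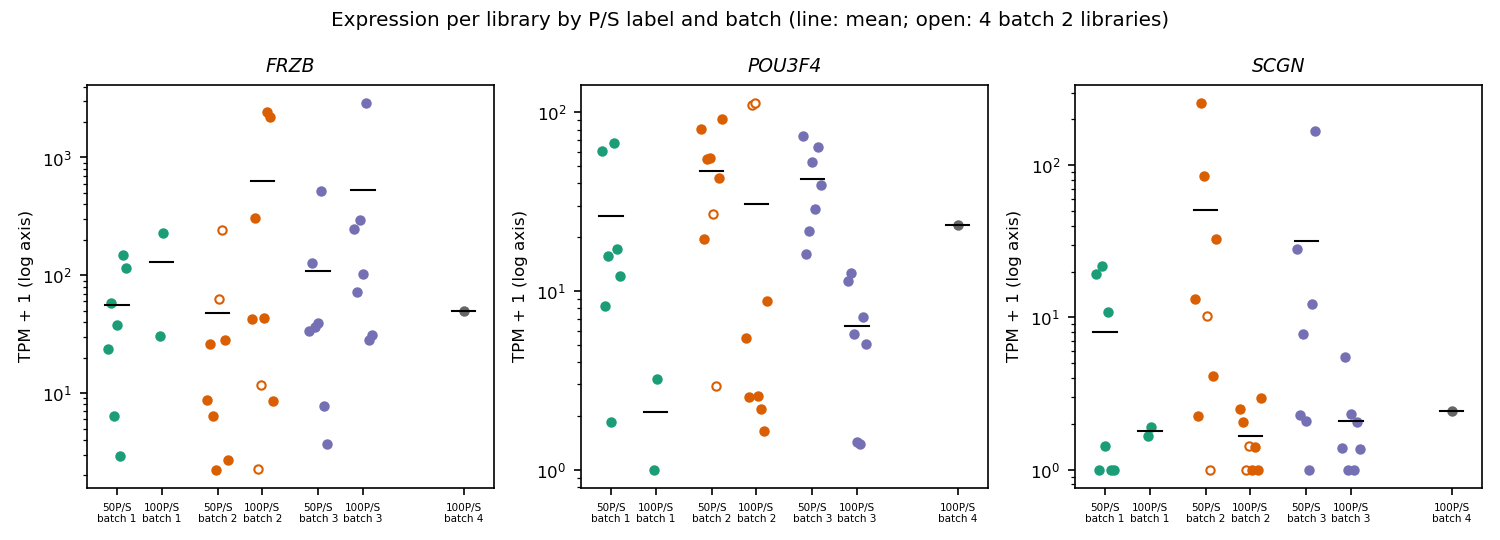
TPM (log axis of TPM + 1) of FRZB, POU3F4 and SCGN in each library by batch, 50P/S and 100P/S side by side, with bars at the mean of each label and batch, where batch 4 holds 1 library. The log2 difference of SCGN, 100P/S against 50P/S, is -2.28 over all batches, and -1.14, -3.10 and -2.20 within batches 1, 2 and 3.

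Astrocyte co-culture was compared with none in DCX+ cells to ask whether it changes the neurons. At D54 (6 against 7 libraries) SST was 10686 ± 5447 TPM with astrocytes and 10756 ± 7592 without, GAD1 419 ± 266 and 365 ± 206, LHX6 44.8 ± 22.7 and 48.3 ± 19.01, and DCX 127 ± 19.6 and 99.8 ± 27.7. By limma 0 genes passed, with 551 at an unadjusted p under 0.05, and 0 without the 4 libraries, with 515. The log2 fold changes of DLX2 (0.11 ± 0.47), NKX2-1 (-0.66 ± 0.79), SOX2 (0.16 ± 0.29) and MKI67 (-0.15 ± 0.41) were below 2 SE. Of the lists 6 were called, all with 0 members past the threshold. Interneuron subtype genes (adjusted p = 0.00394 and adjusted p = 0.8396 with an estimated correlation) and GABA and glycine receptors (adjusted p = 0.0325 and adjusted p = 0.8396 with an estimated correlation) were called upwards. Cholesterol synthesis (adjusted p = 0.00233 and adjusted p = 0.8396 with an estimated correlation) and SHH targets (adjusted p = 0.0325 and adjusted p = 0.5001 with an estimated correlation) were called downwards. Cell cycle (adjusted p = 0.0473 and adjusted p = 0.8396 with an estimated correlation) and mesenchymal genes (adjusted p = 0.0473 and adjusted p = 0.8396 with an estimated correlation) were called downwards too. Cholesterol synthesis stayed called without the 4 libraries (adjusted p = 0.0308). The other 5 did not, with adjusted p = 0.491, 0.763, 0.0546, 0.672 and 0.195 in the order given. Median-of-ratios scaling ended the last 3 as well (adjusted p = 0.0516, 0.0595 and 0.0751), and quantile normalization the mesenchymal call (0.0734).

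At D100 (4 against 5 libraries) SST was 7827 ± 5224 TPM with astrocytes and 5576 ± 2637 without, GAD1 645 ± 268 and 597 ± 183, and DCX 87.2 ± 16.6 and 101 ± 41.4. By limma 0 genes passed, with 250 at an unadjusted p under 0.05, and 0 without the 4 libraries, with 327. The log2 fold changes of LHX6 (-0.25 ± 0.63), DLX2 (0.34 ± 0.57), NKX2-1 (-1.13 ± 0.95), SOX2 (-0.04 ± 0.35) and MKI67 (-0.18 ± 0.49) were below 2 SE. Oligodendrocyte genes were called lower with co-culture (median -0.51, adjusted p = 4.71e-04 and adjusted p = 0.871 with an estimated correlation), with 0 members past the threshold. Cell cycle genes were called lower (adjusted p = 0.02999 and adjusted p = 0.917 with an estimated correlation). Oxidative phosphorylation was called lower too (adjusted p = 0.0477 and adjusted p = 0.871 with an estimated correlation), but not with a replicate block (adjusted p = 0.225), median-of-ratios scaling (0.0983) or quantile normalization (0.306). LGE and CGE factors were called higher (adjusted p = 0.02999 and adjusted p = 0.871 with an estimated correlation). A different effect of co-culture at D100 and D54 passed for 0 genes by limma, with 256 at an unadjusted p under 0.05, and for 0 of 28 lists. Without the 4 libraries 0 genes passed, with 319.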

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

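The tests of the 4 batch 2 libraries, those of the glial transcripts and those of the P/S difference were chosen after the result was seen, except a comparison of called genes set before.

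In 4 of the 84 groups of libraries examined, 1 library stood far from the others, and chance flags about 1 in 20 groups. LHX6 was 3.94 TPM in the 50P/S DCX+ D54 co-culture library of batch 2, where the other 5 held from 40.3 to 68.8 TPM. DLX2 was 186 TPM in 50P/S DCX+ D100 of batch 2, against 52.2 to 62.2 TPM in the other 4. The D100 co-culture library of this label and batch had 3.67 TPM of LHX6 and 206 of DLX2, but the D54 one 60.97 of DLX2. These 2 flags may not be separate. The 100P/S DCX+ D54 co-culture library of batch 3 had 13157 features at 1 TPM or more, against 12278 to 12568 in the other 5. SST was 14655 TPM in the library labelled 100P/S DCX+ D26 of batch 2, against 41.8 to 141 TPM in the other 4, and this library belongs to the first pattern weighed. The difference between the fractions in their change from D26 to D100, which passed for 333 genes, stood out as an effect that differs between groups.

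The 4 libraries of batch 2 labelled 50P/S D54 and 100P/S D26 stood with the other day. An exchange of day labels between the 2 cultures requires both fractions of each culture to be out of place, and 4 of the 4 libraries were nearer the other day, against 0 of the 18 others, with genes picked each time without the library scored and without the 4. If whole cultures were exchanged, all 4 would also be nearer the other P/S label. By a score within labelled states 3 were, with 1 of the 12 other batch 2 libraries misplaced. Those states are in doubt for the 4, so this cannot be told apart. Low library quality is argued against, since 4 of the 4 had a number of features at 1 TPM or more (12327, 12606, 11943 and 12649) inside the range of the others of their fraction. Cultures that developed at another pace stay open and were not tested.

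The rise of glial transcripts in DCX+ libraries at D100 was weighed next. Carry-over of DCX- cells into the DCX+ gate would bring every abundant DCX- transcript at a like share, and the median share implied by 7 astrocyte genes (23.0%, quartiles 18.3% and 34.3%) was 1.29 times that of 279 other abundant DCX- genes (17.9%, quartiles 12.6% and 24.1%), as carry-over needs. But of 2535 genes with at least 50 TPM in every DCX- D100 library, CTGF and IGFBP7 stood under 50% of the level needed in all 3 cultures sorted into both fractions. They had 5.17 ± 5.49 and 17.7 ± 16.5 TPM in DCX+ (3.63% and 5.25% of DCX-), and TAGLN and GDF15, lower in DCX+ too, stood at 4.04% and 6.68%. So few genes do not decide, and carry-over, even or of some DCX- cells, and DCX+ cells that share this program cannot be told apart. An even carry-over, but not that of some DCX- cells, is argued against for oligodendrocyte transcripts. The 4 genes examined had higher means in DCX+ at D100: MBP (109.7 ± 105 against 8.57 ± 5.61 TPM), MAG (22.5 ± 22.8 against 0.91 ± 0.81), CLDN11 (40.7 ± 43.8 against 2.12 ± 1.68) and SOX10 (5.14 ± 6.18 against 0.27 ± 0.24). Astrocytes added to the co-culture are excluded as the whole source, since GFAP rose by 5.65 on the log2 scale from D54 to D100 in libraries without them. A candidate explanation left open for these 4 genes is that oligodendrocyte lineage cells passed the DCX+ gate at D100.

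The P/S difference was weighed against batch 2, which holds 16 of the 40 libraries. A comparison of the folds of the 165 called genes inside and outside batch 2, set before, decides nothing, since these were chosen over all libraries and lean towards the same sign in each part. A difference owed to 1 line of cultures in batch 2 would leave genes picked there with no common sign elsewhere. Of 100 genes picked in batch 2 alone, 77 had the same sign in the other batches, with a median log2 fold of 0.25 there against 1.16 in batch 2. With labels shuffled among whole cultures outside batch 2, 1 of 100 splits, the real one, reached this median (highest other 0.199). This parts the days of a line, so batch 2 as the whole source stays open. Alone, libraries outside batch 2 gave 1 call by limma and those in batch 2 gave 0, with 2362 genes at an unadjusted p under 0.05. The 4 batch 2 libraries are argued against as the whole source, since 366 genes were called without them, although 56 of the 165 were not among these. Whether the P/S label stands for a treatment whose effect this is stays open, and no biological explanation was tested.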

How the results depend on the processing

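The alternatives were set before the data were examined, except leaving out the 4 batch 2 libraries and a random term by culture for P/S, which were chosen after seeing the data. TPM keeps no depth, so the counting error of low values is unknown, and the p-values measure only the spread between libraries. Counts within 1.5 times the reported one are not listed, the replicate block by batch number changed no count beyond that, and the cause of the changes was not tested except where fewer libraries or genes were used. Settings by batch had no value where a batch lacks a group, as for batch 3 and DCX- at D100. With a pseudocount of 0.1, 657 genes were called for D100 against D54 in DCX-, 96 for P/S and 192 for the difference of the D26 to D100 change between fractions, and 613 for the last with a pseudocount of 5. Without a filter P/S gave 107 and co-culture at D100 gave 4. Median-of-ratios scaling gave 1 gene for the P/S difference between fractions, quantile normalization 255 for D54 against D26 in DCX-, and the 16 label combinations 1 for co-culture at D100. With only the libraries compared the sort at D26 gave 2191, D54 against D26 gave 0 in DCX+ and 0 in DCX- by limma, with 2369 and 2397 genes at an unadjusted p under 0.05, and the difference between fractions 141. In batch 2 only, the sort gave 1588, 450 and 545 genes at the 3 days, D54 against D26 gave 3 in DCX+ and 1 in DCX-, D100 against D54 gave 0 and 93, P/S 0, and the differences over time and of P/S between fractions 3 and 1, where the counts of 0 by limma had 1067 and 2362 genes at an unadjusted p under 0.05. In batch 3 only, the sort at D26 gave 2447, D54 against D26 gave 2335 in DCX+ and 1587 in DCX-, P/S 9, co-culture 7 and 1 at D54 and D100, its difference between days 1, and the P/S difference between fractions 2. A block by culture gave 2500 for the sort at D26. A random term by culture gave 77 for P/S, and P/S gave 0 in only DCX+ without astrocytes, only DCX- and only co-culture libraries. Without the 4 libraries D54 against D26 gave 3519 in DCX+ and 2698 in DCX-, P/S 366 and the difference between fractions 898. Of 364 list tests 113 were called, and 19 with the estimated correlation.

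Leaving out 1 library gave counts from 3583 to 3969 for the sort at D26, 4352 to 5117 at D54 and 1832 (without 100P/S DCX- D100 replicate 2) to 2994 at D100. D54 against D26 gave 473 to 1848 in DCX+ and 68 to 1188 in DCX-, and D100 against D54 gave 556 to 871 and 568 to 1025, the libraries being named with each comparison. P/S gave 75 to 249, co-culture 0 to 0 at D54 and 0 to 1 at D100 (without 100P/S DCX+ D100 co-culture replicate 3). The difference between fractions over time gave 119 to 531, that of co-culture 0 to 0, and that of P/S 0 to 5 (without 100P/S DCX- D26 replicate 3). Of the named genes called by the labels or the setting, NKX2-1 reversed for D54 against D26 in DCX+ in batch 3 only (-1.50). Genes called in neither changed sign in 51 values, such as LHX6 for P/S, from -0.14 to 1.26 in the co-cultures only. Over the settings set before, the named genes stayed on their side of the threshold in 2523 values, lost the call in 329 and gained one in 12. Leaving 1 library out, these numbers were 3137, 254 and 7, without the 4 libraries 246, 2 and 5, and with the random term 22, 4 and 0. Of the 113 called lists 0 medians changed sign under either scaling, while 10 calls were lost with median-of-ratios scaling and 14 after quantile normalization, each named with its list. Without 1 library the fold of 8 of 28 named calls of the sort at D26 moved by over 1.5 times, of 6 of 30 at D54 and of 12 of 26 at D100. For D54 against D26 it was 13 of 22 in DCX+ and 15 of 20 in DCX-, for D100 against D54 1 of 27 and 10 of 23, and for P/S 0 of 18. Quantile normalization moved the median of all genes by -0.10, -0.15, -0.15 and -0.11 (log2) in the 4 comparisons over time and by 0.12 for the P/S difference between fractions, and median-of-ratios scaling by -0.11 for D54 against D26 in DCX- and 0.14 for the last.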

Other observations

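The splits of the comparisons as labelled were planned, and those without the 4 batch 2 libraries and by whole cultures were chosen after the result was seen.

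Co-cultured DCX+ libraries were not compared between days in a test of their own. Their GFAP level was 11.04 ± 14.1 TPM at D54 (n = 6), against 0.130000 ± 0.177 TPM in DCX+ libraries without astrocytes (n = 7), and 98.3 ± 68.4 TPM at D100 (n = 4), AQP4 0.587 ± 0.723 and 101 ± 80.2 TPM, and MBP 2.58 ± 2.43 and 77.4 ± 65.2 TPM. The interneuron peptide genes stood at 10686 ± 5447 and 7827 ± 5224 TPM for SST and 2504 ± 2197 and 1089 ± 799 TPM for NPY. HMGA2, a gene of early progenitors, had 19.9 ± 9.76 TPM in DCX- at D26 (n = 5), 6.79 ± 5.95 at D54 (n = 5) and 0.157 ± 0.138 at D100 (n = 3). Without the 4 batch 2 libraries the first 2 levels were 23.96 ± 3.97 (n = 4) and 4.43 ± 3.18 TPM (n = 4). These genes were chosen after their values were seen.

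Other groupings of the same libraries were refitted to ask whether chance gives as many genes. For the sort at D26, D54 and D100, 1 of 100, 1 of 100 and 1 of 56 splits, the real one, reached the real counts of 4023, 4932 and 3100, the highest others calling 1864, 2240 and 749, so chance was excluded. For D54 against D26 in DCX+ it was not, as 7 of 100 splits called at least the 919 genes of the labels. The highest, 2092, exchanged 2 of the 4 batch 2 libraries. Without these libraries the real split called 3519 genes, 1 of 100 splits reached this and the highest other gave 2225. In DCX- 2 of 100 splits reached 389 genes, but the highest other called 545, so chance was not excluded. That split exchanged 1 of the 4 batch 2 libraries. Without the 4, 1 of 35 reached 2698 (highest other 104). Chance was excluded for D100 against D54 in DCX+ (1 of 100 splits, 885 genes, highest other 151). It was also excluded in DCX- (1 of 56, 1031, 162). For the difference between fractions over time (3 of 100, 333, 1296) it was not excluded. The highest split there called several times the real count and exchanged 1 of the 4 batch 2 libraries. For P/S 1 of 100 splits of single libraries reached 165 genes (highest other 1), but these part the fractions of a culture. With whole cultures kept together, which still parts the days, 2 of 100 splits reached 165 (highest other 347), so chance was not excluded. For the counts of 0 by limma, all 100 splits reached 0, with highest others of 41 for co-culture at D54, 36 at D100, 48 for its difference between days and 7 for the P/S difference between fractions, and 551, 250, 256 and 1066 genes at an unadjusted p under 0.05.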
